A study of Mus musculus with 6 samples.

How the data were processed

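The data were 2 tables of the whole series, covering 3 WT and 3 Tdp2 cKO libraries from cortex at 6 months. Tissue was flash frozen, RNA was extracted with Trizol, and paired-end libraries were made from polyA RNA with an RNA integrity score of 8 or higher, per the labels' protocols. The first table held counts per gene, whole numbers that the authors deposited without normalization. The submitters' processing notes name FastQC, Trimmomatic, TopHat, HTSeq, DESeq2 and deepTools, with no versions, and the builds mm10 and GRCm38.p6. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain. The second table held TPM, which the authors deposited and which sum to 1000000 in each library. Dividing counts by TPM showed that the authors used the genomic span of each gene, introns included, as its length (coefficient of variation of the ratio 2.6e-08% over 12873 genes). The span was a median of 5.59 times the exonic length in GENCODE M21, and 52.6% of tested genes would move by more than 2-fold relative to TPM on exonic length. TPM therefore entered only as an alternative within genes, as log2(TPM + 1). The added 1 keeps the length from cancelling for genes of low TPM, and 1389 tested genes (9.21%) had a mean TPM under 1. The choroid plexus median was 1.62 on this scale. All columns were mapped to samples by their names, and 0 were left unmapped.

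Gene starts and ends in the tables equalled those of GENCODE M21 (GRCm38) for 899 of 33331 gene IDs (2.70%), so the tables' positions belong to another annotation or build. Coordinates given here are those of GENCODE M21, matched by Ensembl ID, for which 33331 of 33331 IDs matched. No mitochondrially encoded gene was in the table, so the list of such genes fixed beforehand was not tested.

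Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling and the robust quasi-likelihood test with genotype as the 1 term, over all 6 libraries. P-values were adjusted by Benjamini and Hochberg over the 15080 genes tested, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. CPM are TMM-scaled, and log2 CPM had a prior count of 2. The biological coefficient of variation was 12.9%. Depth ran from 14067465 to 19985784 counts per library, with 19834 to 20573 genes detected. Every pair of libraries differed by more than sampling noise, with chi-square values per gene from 7.31 to 30.2. Nothing in the labels says beyond the replicate number that the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

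Gene lists for the activity response, cell types, synapse, channels, DNA damage and neighbouring tissue were fixed before the data were examined. Each list with 5 or more members tested was compared with all other genes by camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and adjustment over 33 lists, and again with an estimated correlation and with fry. A list's score in a library is the mean over its members of log2 CPM minus the WT mean. Genes named were set by a rule: Tdp2 first, then genes past the threshold with non-overlapping groups, and, where fewer than 10 passed in a direction, the 5 smallest p-values in it with a mean CPM of 1 or more. Symbols of predicted genes were left out by the rule. Of the genes this rule set, 1 is not reported here. Up to 4 members of a list were named by smallest p, and members of the early response and repair lists freely. Lhx9, 1700016P03Rik and Ttr lay outside this rule and were chosen after their values were seen. Where members were named was also settled then.

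The test was tried on simulated data with the real genes' means and library sizes and 200 changed genes, for cKO against WT with 3 and 3 libraries (14923 genes tested). It recovered 32.8% of genes changed 1.5-fold, 73.1% changed 2-fold and 98.5% changed 4-fold, with 10 false calls, 6.85% of all calls. With no change simulated (14925 genes), 2 genes and 0 lists passed. Simulated genes varied independently, so the simulation leaves out differences between libraries that many genes share. In the splits of the 6 real libraries that mix the genotypes, 6 to 19 lists passed.

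Alternatives fixed before the data were examined were RLE, upper quartile and library size scaling, no filter and a filter at CPM 1 in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), leaving out each library in turn, a replicate block, sex read from Xist and the Y-linked genes as a covariate, leaving out X, Y and haemoglobin genes, an adjusted p of 0.1, a change of at least 1.5-fold, the estimated correlation, and the length implied by counts and TPM. Added after seeing the data were a fit without robust estimation, the choroid plexus or striatal score as a covariate, leaving out the 2 cKO libraries with choroid plexus transcripts, and exonic length. Attention to the late response and ion channel lists among the 33 was also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.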

Results

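PolyA RNA was sequenced from cortex of 6-month-old C57BL/6 mice of 2 genotypes, with 3 libraries each. The wild-type (WT) mice carried floxed Tdp2 alleles without Cre, and the conditional knockout (cKO) mice carried the same alleles with a CAMKII:Cre driver, which acts in forebrain excitatory neurons. Tdp2 encodes the enzyme that removes topoisomerase 2 trapped on DNA ends, and the series title names early response gene transcription as the question. Total counts were 15240398, 19985784 and 16461953 in WT replicates 1, 2 and 3, and 16328899, 14067465 and 15301304 in cKO replicates 1, 2 and 3. The table held 33331 genes, of which 15080 had enough counts to be tested. On principal component 1, which held 43.1% of the variance, cKO replicate 3 lay at 40.1 and the other 5 libraries between -22.3 and 6.01.

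Tdp2 (ENSMUSG00000035958, chromosome 13, 24831679 to 24842153, GRCm38) was not lower in the libraries labelled cKO. Its counts were 343, 376 and 323 in the WT libraries and 453, 284 and 281 in the libraries labelled cKO. Expression was 20.5 ± 2.11 counts per 1000000 (CPM) in WT and 22.0 ± 5.16 CPM in cKO (SD, n = 3 each). The log2 fold change was 0.10 with a standard error (SE) of 0.16, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.998. A 95% interval of the ratio, from that SE and a t distribution with 4 degrees of freedom, ran from 0.786 to 1.47. edgeR's test also borrows degrees of freedom across genes, so this interval is wider than that test implies. An exact two-sided permutation test on CPM gave p = 0.8, where 3 libraries against 3 cannot go below 0.1. Without cKO replicate 1 the log2 fold change was -0.10. Counts over a whole gene cannot show the loss of a floxed exon, and Cre acts in part of the cells of cortex, so this value checks the labels weakly. Genotypes below are those of the labels.

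**Figure D1:**
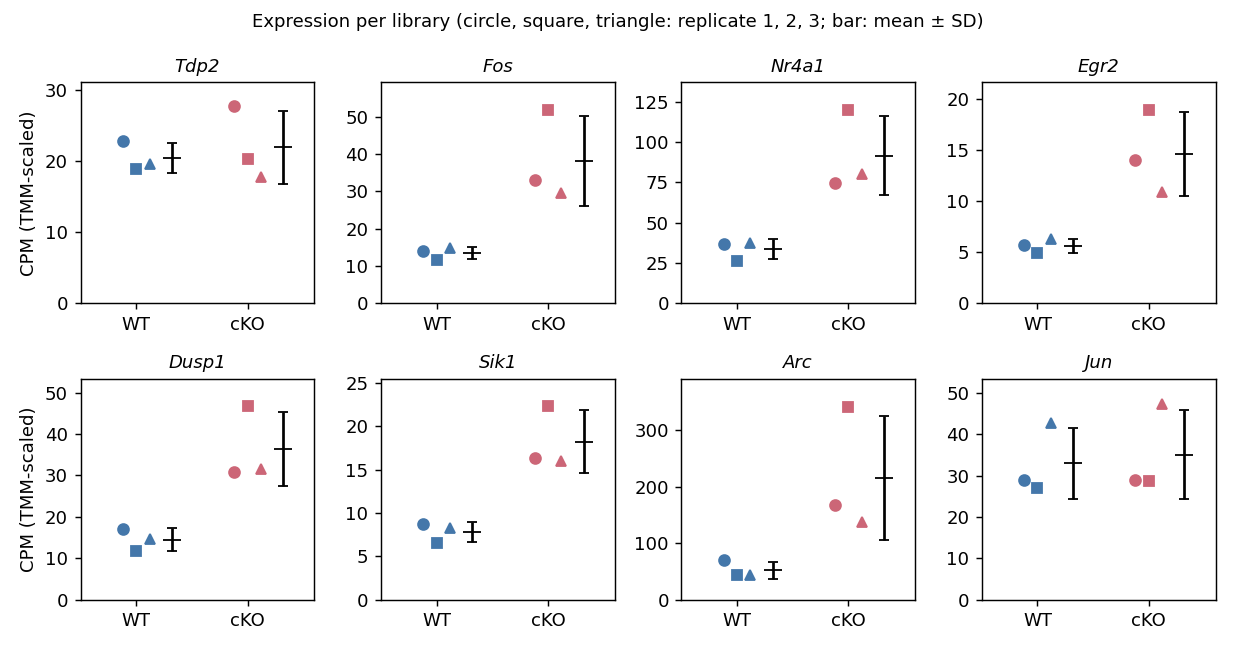
Expression in CPM of Tdp2, 6 early response genes that were higher in the libraries labelled cKO (Fos, Nr4a1, Egr2, Dusp1, Sik1 and Arc) and Jun, for each of the 3 WT and 3 cKO libraries. Circles, squares and triangles are replicates 1, 2 and 3, and the bar beside each group is its mean ± SD; every cKO library lies above every WT library in those 6 panels, while the groups overlap for Tdp2 and Jun.

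Early response genes, which neurons transcribe within minutes of activity, were higher as a group in the libraries labelled cKO. Of 34 members tested, 33 were higher and 1, Amigo3, was lower, with a median log2 fold change of 0.65, or 1.56-fold. Relative to the WT mean, the list averaged 0.05, -0.11 and 0.07 on the log2 scale in the WT libraries and 0.60, 0.97 and 0.53 in the libraries labelled cKO. For 18 members every cKO library lay above every WT library, where chance gives 10% of genes a separation in either direction. Arc, a synaptic plasticity effector, was at 51.8 ± 15.3 CPM in WT and 215 ± 109 CPM in cKO (SD, n = 3 each), with a log2 fold change of 2.05 (SE 0.44). Fos, a subunit of the AP-1 transcription factor, went from 13.5 ± 1.64 to 38.2 ± 12 CPM, with a log2 fold change of 1.5 (SE 0.22). The nuclear receptor gene Nr4a1 went from 33.5 ± 6.09 to 91.5 ± 24.7 CPM, and Junb, another AP-1 subunit, from 16.4 ± 4.94 to 40.2 ± 6.38 CPM. Dusp1, a phosphatase of MAP kinases, went from 14.5 ± 2.73 to 36.3 ± 9.01 CPM.

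The members with the smallest p were Sik1, Egr2 and Btg2. Sik1 (salt-inducible kinase, ENSMUSG00000024042, chromosome 17, 31844250 to 31855804) went from 7.84 ± 1.14 to 18.2 ± 3.59 CPM, a log2 fold change of 1.22 (SE 0.17). Egr2 (zinc finger transcription factor, ENSMUSG00000037868, chromosome 10, 67535475 to 67542188) went from 5.61 ± 0.688 to 14.6 ± 4.07 CPM, a log2 fold change of 1.38 (SE 0.21). Btg2 (antiproliferative regulator, ENSMUSG00000020423, chromosome 1, 134075170 to 134079120) went from 7.72 ± 0.626 to 16.1 ± 3.38 CPM, a log2 fold change of 1.07 (SE 0.17). Npas4, a neuron-specific early response transcription factor, was higher by a smaller amount, at 10.3 ± 0.644 and 15.6 ± 2.08 CPM. Not every member was apart: Egr1 was at 360 ± 18.3 CPM in WT and 518 ± 227 CPM in cKO with overlapping groups, and Jun, Arf4 and Fbxo33 had log2 fold changes of 0.09, 0.02 and 0.01.

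In edgeR's test, 17 members had an adjusted p under 0.05 when adjusted over the list alone, all 17 higher, and 0 had one when adjusted over all genes tested. The list passed camera with a preset inter-gene correlation (adjusted p = 2.5e-57 over 33 lists). With an estimated correlation of 0.24 its p was 0.0034 and its adjusted p = 0.11, and fry, which asks whether the members move one way on balance, gave p = 0.0096 and an adjusted p of 0.32. Without cKO replicate 3, the 1 male library of the 6, 6 genes had an adjusted p under 0.05 over all genes, and all 6 were on this list: Egr2, Sik1, Fos, Fosl2, Klf10 and Egr1.

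**Figure D2:**
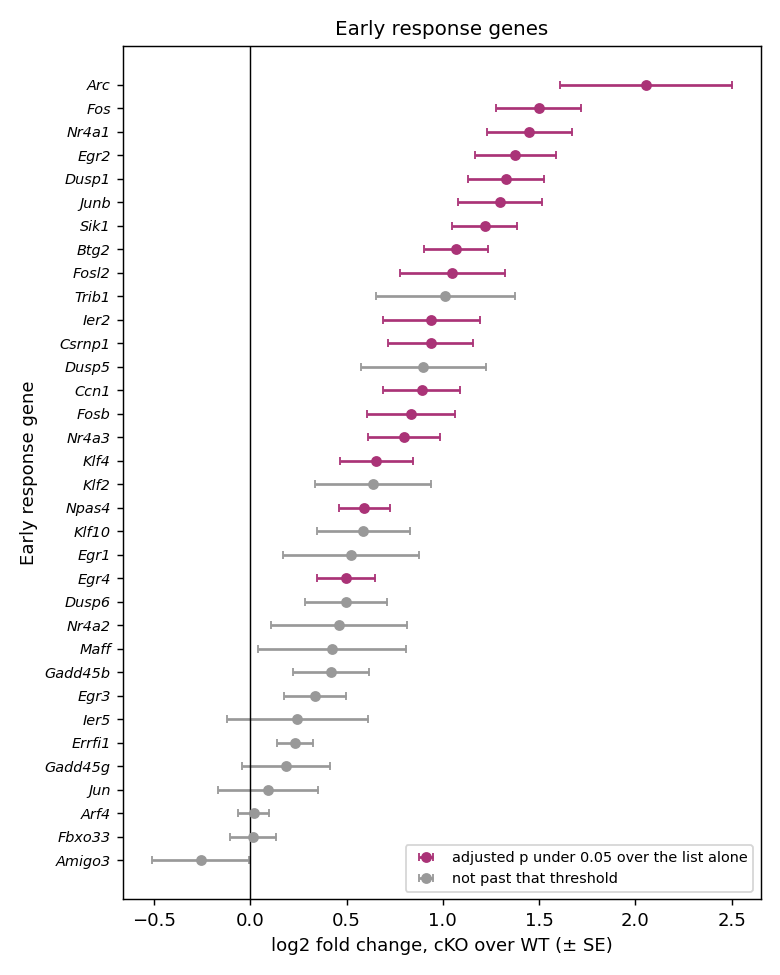
Log2 fold change, libraries labelled cKO over WT, of the 34 early response genes tested, with bars of ± 1 SE from edgeR (n = 3 libraries per genotype). The 17 genes with an adjusted p under 0.05 over the list alone are coloured, and the values run from -0.26 for Amigo3 to 2.05 for Arc.

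Across all genes, 0 of 15080 had an adjusted p under 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.233. At an unadjusted p under 0.05 there were 530 genes, 309 higher and 221 lower, where 754 would be expected by chance. limma-voom also gave 0 genes, and DESeq2 gave 15, of which 14 were higher. Of those 15, 10 were on the early response list and 1, Tiparp, on the late response list. The other 4 were Sox8, Lhx9, 1700016P03Rik and Kcnq3. Groups did not overlap for 607 genes with cKO above and 637 with cKO below, together 8.25% of genes, where chance gives 10%.

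With predicted-gene symbols such as 1700016P03Rik (adjusted p = 0.233 by edgeR) left out, the 5 genes with the smallest p among those higher in the libraries labelled cKO were Sik1, Tiparp, Egr2, Btg2 and Sox8. Tiparp (a poly-ADP-ribose polymerase family member, ENSMUSG00000034640, chromosome 3, 65528410 to 65555518) was at 21 ± 2.23 and 34.3 ± 1.95 CPM, with an adjusted p of 0.233 by edgeR. Sox8 (transcription factor of the oligodendrocyte lineage, ENSMUSG00000024176, chromosome 17, 25565892 to 25570686) was at 33.0 ± 3.52 and 50.1 ± 3.10 CPM. Among those lower, Kcnq3, Frzb, St6gal2 and Chrdl1 had small p-values, and none of them passed edgeR's test. Kcnq3 (subunit of the M-type potassium channel, ENSMUSG00000056258, chromosome 15, 65986387 to 66286642) was at 56.1 ± 3.01 and 40.9 ± 1.29 CPM, with a log2 fold change of -0.46 (SE 0.08). Frzb (secreted Wnt inhibitor, ENSMUSG00000027004, chromosome 2, 80411970 to 80447625) was at 27.8 ± 1.52 and 19.2 ± 1.04 CPM. St6gal2 (sialyltransferase, ENSMUSG00000024172, chromosome 17, 55445382 to 55514581) was at 96.5 ± 5.75 and 74.4 ± 3.96 CPM. Chrdl1 (secreted BMP antagonist, ENSMUSG00000031283, chromosome X, 143285674 to 143394262) was at 47.4 ± 3.57 and 35.1 ± 3.42 CPM.

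Late activity response genes, which follow the early wave, were also higher on balance: 22 of 25 members, with a median log2 fold change of 0.20. The list's scores were 0.10, -0.06 and -0.03 in WT replicates 1, 2 and 3. In cKO replicates 1, 2 and 3 they were 0.28, 0.42 and 0.01, so cKO replicate 3 lay below WT replicate 1. Tiparp was the 1 member past an adjusted p of 0.05 over the list alone. Nptx2, a secreted pentraxin at synapses, was at 28.8 ± 5.16 CPM in WT and 39.7 ± 3.75 CPM in cKO, and the neurotrophin gene Bdnf at 38.7 ± 5.24 and 52.9 ± 10.4 CPM. The list passed camera at the preset correlation (adjusted p = 1.5e-08) and had an adjusted p = 0.42 with an estimated correlation. Its median was 0.11 without cKO replicate 2 and 0.36 without cKO replicate 3. It was 0.45 with the choroid plexus score of each library as a covariate (adjusted p = 2.9e-24) and 0.31 with the striatal score (adjusted p = 3.5e-10). Without cKO replicates 1 and 3 it was 0.38. The choroid plexus score was high only in those 2 libraries. For every list, the fit with that score and the fit without those libraries therefore rest mainly on cKO replicate 2. That library had the highest late response score, 0.42.

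Genes of neuronal excitability and the synapse were slightly lower on balance in the libraries labelled cKO. Of 39 voltage-gated ion channel genes, 32 were lower, with a median log2 fold change of -0.18, and Kcnq3 was the 1 member past an adjusted p of 0.05 over the list alone. By the list's score the groups overlapped, with WT replicate 3 at -0.072 and cKO replicate 2 at -0.068, and cKO replicate 3 was lowest at -0.301. Kcnma1, the large-conductance calcium-activated potassium channel, was at 162 ± 7.35 and 135 ± 14.3 CPM, and Kcnip4, which binds A-type potassium channels, at 88.1 ± 3.16 and 76.2 ± 6.12 CPM. Of 34 presynaptic genes 30 were lower (median -0.09), among them Rims2 at 141 ± 6.42 and 120 ± 1.76 CPM and the calcium sensor Syt1. Of 36 postsynaptic genes 27 were lower (median -0.06), among them the receptor subunit genes Grin2a and Gabrb2. Clustered protocadherin genes, whose near-identical copies make their counts uncertain, were lower for 18 of 23 members (median -0.18), and excitatory cortical neuron markers for 18 of 27 (median -0.10), including Mef2c and Tbr1. At the preset correlation camera gave adjusted p-values of 9.9e-10 for channels, 2.0e-04 for presynaptic, 6.1e-04 for postsynaptic, 1.6e-04 for protocadherin and 0.0046 for excitatory marker genes. With an estimated correlation the adjusted p = 0.42 for channel, presynaptic and excitatory marker genes, 0.50 for postsynaptic and 0.51 for protocadherin genes. By their scores the groups also overlapped for the postsynaptic, protocadherin and excitatory marker lists. Presynaptic scores were apart by little, with WT replicate 2 at -0.018 and cKO replicate 2 at -0.020. Without WT replicate 3 or cKO replicate 3 the excitatory markers did not pass, with medians of -0.06 and -0.07. The protocadherin median was -0.11 without WT replicate 1, -0.29 without cKO replicate 1 and -0.09 without cKO replicate 3, and the postsynaptic median was -0.10 without WT replicate 2. The channel median was -0.29 without cKO replicate 2 and -0.10 without cKO replicate 3, and it was -0.03 (adjusted p = 0.073) with the choroid plexus score of each library as a covariate. The other 4 lists did not pass with that covariate either, with medians of -0.04 for presynaptic (adjusted p = 0.29), -0.01 for postsynaptic (0.26), -0.10 for protocadherin (0.16) and -0.03 for excitatory marker genes (0.56). With the striatal score as a covariate the postsynaptic genes did not pass (median -0.03, adjusted p = 0.12). With sex as a covariate, which in effect leaves out the male cKO replicate 3, the excitatory markers did not (median -0.07, adjusted p = 0.16). Without both cKO libraries with choroid plexus transcripts, where 1 cKO library remains, the channel median was -0.05. In that fit the presynaptic, postsynaptic and excitatory marker medians were -0.04, -0.02 and -0.01, while the protocadherin median was -0.20.

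Transcripts of tissue that borders the cortex differed between libraries. Choroid plexus markers were high in cKO replicates 1 and 3, whose scores were 2.75 and 4.75 on the log2 scale relative to WT, and not in cKO replicate 2, at -0.33. Ttr, the transthyretin gene of choroid plexus, had 2038 and 12289 counts in cKO replicates 1 and 3 against 44, 246 and 162 in the WT libraries and 35 in cKO replicate 2. All 5 tested members were higher (median 3.38, camera adjusted p = 9.1e-06 at the preset correlation and adjusted p = 0.42 with an estimated correlation), and the median was 1.62 without cKO replicate 3. Striatal markers were higher for 11 of 14 members (median 0.26, adjusted p = 0.017, and adjusted p = 0.81 with an estimated correlation), with the highest score, 1.21, in WT replicate 2. Foxp1, a transcription factor of striatal projection neurons, was at 199 ± 22.6 and 162 ± 41.5 CPM, and the developmental regulator Six3 at 1.33 ± 1.74 and 4.22 ± 3.40 CPM. The striatal list did not pass without WT replicate 1, WT replicate 3 or cKO replicate 2, with medians of -0.07, 0.06 and 0.20, and its median was 0.89 without WT replicate 2. It did not pass with DESeq2 (median 0.26, adjusted p = 0.16), with the choroid plexus covariate (0.20, adjusted p = 0.15) or without cKO replicates 1 and 3 (0.23, adjusted p = 0.15). Neuropeptide genes, 11 of whose 20 tested members stand on other lists too, were higher for 14 (median 0.20, adjusted p = 0.020, and adjusted p = 0.51 with an estimated correlation), and did not pass without WT replicate 1 or cKO replicate 2, with medians of 0.13 and 0.09. Their median was 0.30 without cKO replicate 1 and 0.05 without cKO replicate 3, and they did not pass with a filter at CPM 1 (0.18, adjusted p = 0.078) or the striatal covariate (0.11, adjusted p = 0.28). Neurotensin (Nts) was at 0.694 ± 0.286 and 2.77 ± 2.89 CPM, and the activity-regulated Vgf at 124 ± 2.76 and 163 ± 48.5 CPM. cKO replicate 3 was also the 1 library with a male pattern, at 16 Xist and 1647 Ddx3y counts, where the other 5 had 14469 to 24759 Xist counts and at most 4 of Ddx3y.

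Among glial and vascular genes, all 17 oligodendrocyte markers were higher in the libraries labelled cKO (median log2 fold change 0.25), led by Ugt8a, of myelin lipid synthesis, at 56.7 ± 15.1 and 75.1 ± 4.03 CPM and the myelin regulator Myrf at 37.9 ± 10.1 and 49.5 ± 3.17 CPM. WT replicate 2 nevertheless had the highest oligodendrocyte score, 0.55, and the list did not pass without WT replicate 1, with a median of 0.05. The median was 0.59 without WT replicate 2 and 0.16 without WT replicate 3. Oligodendrocyte scores ran in the order of the striatal ones in the WT libraries, at -0.42, 0.55 and -0.13 against -0.81, 1.21 and -0.40, and in the opposite order in the libraries labelled cKO, at 0.49, 0.28 and 0.21 against 0.63, 0.67 and 0.79. With the striatal score as a covariate the oligodendrocyte median was 0.0043 (adjusted p = 0.81). Astrocyte markers were higher for 16 of 18 (median 0.13), led by the glycolytic Aldoc at 585 ± 45.0 and 685 ± 38.6 CPM and the transcription factor gene Sox9, and did not pass without WT replicate 1 or cKO replicate 3, with medians of 0.06 and 0.04. They also did not pass with the choroid plexus score (median -0.04, adjusted p = 0.93) or the striatal score (0.06, adjusted p = 0.28) as a covariate. Sex as a covariate (0.04, adjusted p = 0.083) in effect leaves out cKO replicate 3, the 1 male library, and is no separate check. Endothelial and mural markers were lower for 19 of 22 (median -0.08), led by the endothelial sialomucin gene Emcn at 7.97 ± 0.636 and 6.10 ± 0.365 CPM and the transporter gene Slco1a4. They did not pass without WT replicate 2, cKO replicate 1 or cKO replicate 2, with medians of -0.07, -0.06 and -0.07, and the median was -0.14 without WT replicate 1 and -0.15 without cKO replicate 3. With the choroid plexus covariate the endothelial median was -0.20 (adjusted p = 3.7e-05), and it was -0.18 without cKO replicates 1 and 3. Both of these fits rest mainly on cKO replicate 2. Camera's adjusted p-values at the preset correlation were 6.8e-06, 0.0032 and 0.0046 for these 3 lists, and with an estimated correlation the adjusted p = 0.58, 0.51 and 0.51.

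Stress and immune genes went in different directions. Glucocorticoid and stress response genes were higher for 12 of 14 members (median 0.23), led by Plin4 at 1.79 ± 0.132 and 4.17 ± 1.65 CPM and Ddit4 at 14.8 ± 1.80 and 19.5 ± 2.02 CPM. Interferon response genes were lower for 19 of 25 (median -0.12), led by Ifit1 at 4.88 ± 0.678 and 2.89 ± 0.0638 CPM and B2m at 99.2 ± 16.4 and 81.2 ± 5.50 CPM, and did not pass without WT replicate 2 or cKO replicate 2, with medians of -0.10 and -0.10. The interferon median was -0.20 without WT replicate 3 and -0.21 without cKO replicate 1. It was -0.23 with the choroid plexus covariate (adjusted p = 9.2e-04) and -0.28 without cKO replicates 1 and 3. The fits with that covariate and without those libraries rest mainly on cKO replicate 2, whose interferon score was the lowest, -0.35. Ribosomal protein genes, which share reads with pseudogenes, were higher for 71 of 77 (median 0.09), and they did not pass without WT replicate 1 or cKO replicate 3, with medians of 0.03 and 0.02. Their median was 0.13 without WT replicate 3. The ribosomal median was -0.03 with the choroid plexus score (adjusted p = 0.29) and 0.06 with the striatal score (adjusted p = 0.079) as a covariate. With sex as a covariate, which in effect leaves out cKO replicate 3, it was 0.02 (adjusted p = 0.85). Camera's adjusted p-values at the preset correlation were 4.7e-05, 7.4e-04 and 3.8e-05 for these 3 lists, and with an estimated correlation the adjusted p = 0.42, 0.51 and 0.81.

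None of the 3 lists of DNA damage and repair genes passed camera. p53 target genes were higher for 15 of 28 members and lower for 13 (median 0.00, adjusted p = 0.58 by camera), led by the kinase gene Plk3 at 9.52 ± 1.52 and 14.7 ± 3.04 CPM and followed by Ccnd1, Ephx1 and Mdm2, the last at 59.0 ± 3.27 and 63.8 ± 1.49 CPM. Topoisomerase and protein-linked break repair genes were higher for 10 of 18 (median 0.00, adjusted p = 0.70), although their mean was -0.03 and the test pointed down. Within that list Tdp1, which repairs trapped topoisomerase 1, was at 12.9 ± 0.849 and 15.0 ± 1.34 CPM, and Top2b, the topoisomerase 2 of neurons, at 217 ± 11.3 and 204 ± 19.7 CPM. Double-strand break end joining and signalling genes were higher for 13 of 25 (median 0.01, adjusted p = 0.86), with the test pointing down. In simulated data of the same size, 73.1% of genes changed 2-fold and 32.8% of genes changed 1.5-fold were recovered. Simulated genes varied independently, without the differences between libraries that many real genes share, so these shares do not measure what was missed here. Arc, for example, had a log2 fold change of 2.05 and an adjusted p of 0.998 by edgeR in the real data.

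The remaining lists did not pass camera at the preset correlation. Their adjusted p-values and medians were 0.098 and 0.12 for microglia markers, 0.098 and 0.19 for oligodendrocyte precursor markers, 0.10 and -0.04 for nuclear oxidative phosphorylation genes, and 0.11 and -0.06 for axon guidance and cell adhesion genes. They were 0.43 and 0.12 for thalamic and hypothalamic markers, 0.58 and 0.02 for heat shock genes, 0.63 and 0.33 for blood cell genes, and 0.68 and 0.10 for hippocampal markers. They were 0.70 and 0.06 for reactive astrocyte genes, 0.70 and -0.03 for inhibitory neuron markers, 0.70 and -0.02 for meningeal fibroblast markers, 0.73 and 0.00 for histone genes, 0.86 and 0.07 for activated microglia genes, and 0.91 and 0.01 for circadian clock genes. The mean of the inhibitory markers was 0.04 against a negative median and test, and the histone genes had a mean of -0.03 and a test pointing down against a median above 0. Some of these lists passed under alternatives. Axon guidance genes passed in 6, among them DESeq2 (adjusted p = 0.029), without WT replicate 2 (0.020), without cKO replicate 3 (0.010) and the choroid plexus covariate (0.0020), while their median was 0.03 without WT replicate 3 and 0.01 without cKO replicate 2. Oxidative phosphorylation genes passed in 7, among them DESeq2 (0.018), without cKO replicate 2 (0.0013) and the striatal covariate (1.2e-04). Meningeal markers passed without cKO replicate 3 (median -0.36, adjusted p = 3.3e-06), and heat shock genes with the choroid plexus covariate (median 0.13, adjusted p = 7.6e-04). Microglia, oligodendrocyte precursor and thalamic markers passed with DESeq2 (adjusted p = 0.030, 0.031 and 0.014), circadian genes with the choroid plexus covariate (0.0078) and blood cell genes without cKO replicate 1 (0.035). Of 33 lists, 16 passed at the preset correlation, 9 higher and 7 lower, and 0 passed with an estimated correlation or by fry.

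**Figure D3:**
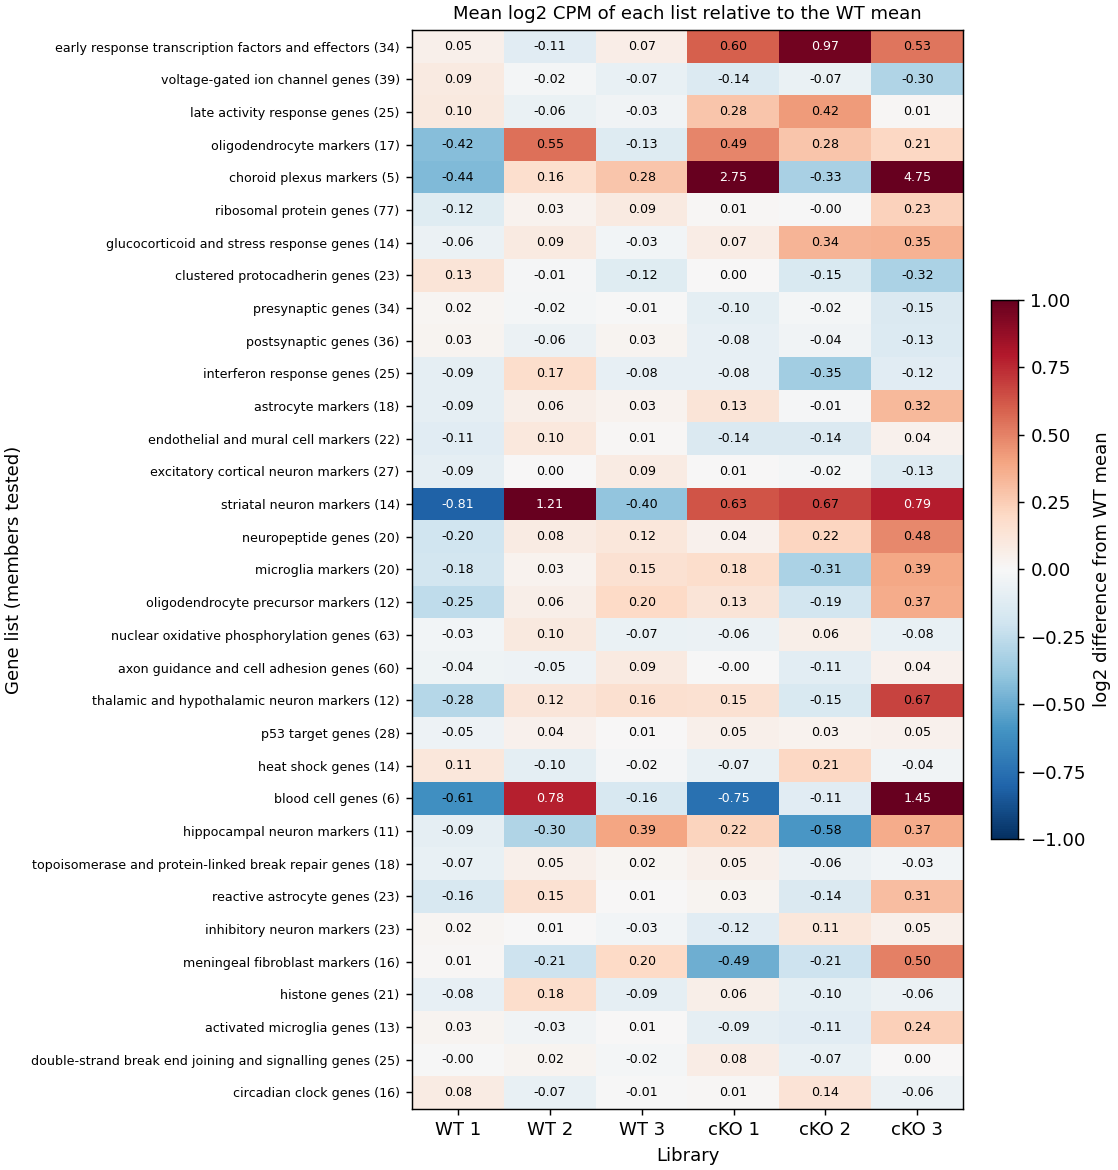
Mean log2 CPM of each gene list in each of the 6 libraries, relative to the mean of the 3 WT libraries, with the number of members tested after each list's name and colours that end at -1 and 1. The early response list lies between 0.53 and 0.97 in the libraries labelled cKO and between -0.11 and 0.07 in WT, and choroid plexus markers stand out in cKO replicates 1 and 3.

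Topoisomerase 2 has been tied to the transcription of long neuronal genes, so fold change was set against gene length. Longer genes were slightly lower in the libraries labelled cKO, with a Spearman correlation of -0.10 across 15080 genes, which are not independent replicates. The median log2 fold change was -0.03 for 2276 genes longer than 100 kb and 0.01 for the others. Camera gave p = 0.0048 for the long genes at the preset correlation and p = 0.11 with an estimated correlation. The correlation was -0.03 without cKO replicate 2 and -0.04 without WT replicate 1. Taken for each cKO library against the WT mean, it had an SD of 0.10 over the cKO libraries. Splits of the libraries that mix the genotypes reached up to 0.19 in size.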

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

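The score covariates, the fit without robust estimation, the fit without both cKO libraries with choroid plexus transcripts and exonic length were added after the data were seen, and the late response and ion channel lists were singled out then. The early response list stayed higher under every alternative, with medians from 0.58 to 0.92 and from 0.55 to 0.80 with a library left out, and passed camera at the preset correlation in each. It did not pass with the estimated correlation or by fry (adjusted p = 0.32). Its members past the threshold over the list alone numbered 16 to 25, and 13 to 25 with a library left out. The correlation with gene length stayed below 0, from -0.16 to -0.04, and from -0.14 to -0.03 with a library left out. Its SD over the cKO libraries, each taken against the WT mean, was 0.10.

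The count of genes past an adjusted p of 0.05 was 0 in edgeR and 0 with limma-voom, limma-trend, the other scalings, the CPM filter and the striatal covariate. It was 7 with no filter, 15 with DESeq2, 6 with sex as a covariate, 19 with the choroid plexus covariate and 21 without cKO replicates 1 and 3, where 1 cKO library remains and is assumed to vary like WT. Leaving out single libraries gave 0 to 6, with 6 without cKO replicate 3. Sex as a covariate removes that library, the 1 male one, by construction. Tdp2's log2 fold change ran from -0.10 to 0.23 with a library left out and was -0.00597 without cKO replicates 1 and 3. With an estimated correlation 0 of the 33 lists passed in place of 16, and the medians of 0.65 (early), 0.20 (late) and -0.18 (channels) had adjusted p-values of 0.11, 0.42 and 0.42. With the choroid plexus covariate the channel median was -0.0323. That score was high only in cKO replicates 1 and 3, so every fit with it rests mainly on cKO replicate 2. The cause of these shifts was not tested unless named.

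Directions of list tests reversed as follows, with the list's median. With no filter and with DESeq2, circadian genes were at -0.000809 and 0.000948 and histone genes at 0.0146 and 0.0224, and with limma-trend on TPM circadian genes were at -0.0145. With sex as a covariate, reactive astrocyte genes were at -0.0187, microglia -0.0443, activated microglia -0.0165, precursors 0.00673, hippocampal -0.0623, thalamic -0.0264 and blood genes -0.625 (adjusted p = 0.0354). With the choroid plexus covariate, inhibitory markers were at 0.0429, reactive astrocyte -0.105, microglia -0.242 (adjusted p = 4.3e-09), activated microglia -0.138, precursors -0.119 (adjusted p = 0.0489), hippocampal -0.616, thalamic -0.369, blood -0.609, oxidative phosphorylation 0.0323 and ribosomal protein genes -0.0290. With the striatal covariate, reactive astrocyte genes were at 0.0167, activated microglia 0.0464, meningeal 0.0924, striatal -0.0505, thalamic 0.101 and blood genes -0.0326. The striatal score is the mean of that list's own members, so the fall of the striatal median was fixed in advance. Without cKO replicates 1 and 3, inhibitory markers were at 0.0484, astrocyte -0.0522, reactive astrocyte -0.0791, microglia -0.273, activated microglia -0.156 and precursors -0.140. In that fit, choroid plexus markers were at -0.262, hippocampal -0.589, thalamic -0.300, blood -0.302, oxidative phosphorylation 0.0601 and ribosomal protein genes -0.00451. Those libraries were left out for their choroid plexus transcripts, so the fall of the choroid plexus median was fixed in advance.

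With single libraries left out, medians of lists whose test reversed ran from -0.0946 to 0.0262 for inhibitory markers, -0.0189 to 0.202 for reactive astrocyte, -0.0446 to 0.290 for microglia, -0.0166 to 0.110 for activated microglia, 0.00650 to 0.278 for precursor, -0.360 to 0.148 for meningeal, -0.106 to 0.226 for hippocampal, -0.0264 to 0.227 for thalamic, -0.622 to 1.03 for blood, -0.0575 to 0.0294 for circadian, -0.0681 to 0.103 for heat shock, -0.0801 to 0.0229 for oxidative phosphorylation, -0.0950 to 0.0988 for histone and -0.0157 to 0.00842 for end joining genes. The axon guidance median ran from -0.0883 to 0.0296, with no reversed test. None of these 15 lists passed camera in the comparison of all 6 libraries, and several passed with 1 library left out, for example microglia markers without cKO replicate 2 at an adjusted p of 1.03e-07.

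Deviations of same-numbered libraries correlated at 0.05, 0.02 and 0.40, the last being the highest of any pair. cKO replicate 1 correlated best with WT replicate 1, though at 0.0517 against 0.0510 for WT replicate 2. cKO replicate 2 correlated best with WT replicate 1, at 0.30. With 3 libraries per genotype, these values cannot tell whether the replicate numbers pair the libraries. With the replicate number as a block, 0 genes, 20 early response members and 16 lists passed, and the test of circadian genes reversed at a median of 0.00863. Of the lead values under alternatives, 165 kept direction and side of the threshold, 7 counts moved, 4 lost the threshold and 2 reversed. Of the other values 694 kept both, 70 reversed, 51 lost and 51 gained the threshold.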

Other observations

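Among tests in this part, those of neighbouring tissue, the male library, stress, neuron share, carried-over tissue and genotype were chosen after the values were seen. The transcript 1700016P03Rik (ENSMUSG00000085609, chromosome 11, 75172560 to 75177633, GRCm38) contains Mir212 (75173388 to 75173478) and Mir132 (75173682 to 75173747), microRNAs known to be induced by neuronal activity. It was at 2.55 ± 0.638 CPM in WT and 8.35 ± 2.16 CPM in the libraries labelled cKO (SD, n = 3 each), a log2 fold change of 1.71 (SE 0.25), with an adjusted p of 0.233 by edgeR and 8.5e-06 by DESeq2. All 3 cKO libraries lay above all 3 WT libraries. The microRNAs themselves are not measured by polyA counts of the host.

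Per1 and Plk3, picked after their values were seen, have been described to respond to neuronal activity. The clock gene Per1 was at 70.0 ± 9 CPM in WT and 107 ± 28.7 CPM in cKO, although the circadian list had a median of 0.01, and the kinase gene Plk3 was at 9.52 ± 1.52 and 14.7 ± 3.04 CPM, although the p53 list had a median of 0.00. Both separated the groups, and both had an adjusted p of 0.998 by edgeR. The homeobox gene Lhx9 was at 0.251 ± 0.0618 CPM in WT and at 1.16, 1.36 and 3.61 CPM in cKO replicates 1, 2 and 3.

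Early response genes were higher in the libraries labelled cKO. Striatal tissue and the male library were argued against. The list's median, 0.65, was 0.78 with the striatal score as a covariate and 0.80 among the 5 female libraries. The median was also higher with the choroid plexus score as a covariate. That score was high only in cKO replicates 1 and 3, so its fit leaves mainly cKO replicate 2, whose early response score was the highest, 0.97. That fit therefore cannot decide on choroid plexus tissue. The scores themselves argue against such tissue for cKO replicate 2 alone, whose choroid plexus score was -0.33. Choroid plexus scores were 2.75 and 4.75 in cKO replicates 1 and 3, with early response scores of 0.60 and 0.53. For those libraries choroid plexus tissue stays open. Hippocampal, thalamic and meningeal scores were not tried, so tissue from those regions stays open. Stress or handling before collection stays open, because the glucocorticoid and stress list had a median of 0.23 but lay above every WT library in 2 of 3 cKO libraries, and the labels give no time or order of collection. Loss of Tdp2 may raise these transcripts, as the genotype of the labels. It cannot be told apart here from such handling, or from Cre itself, which only the cKO mice carried.

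Voltage-gated ion channel genes were lower on balance in the libraries labelled cKO. Their scores were 0.088, -0.017 and -0.072 in WT replicates 1, 2 and 3. In cKO replicates 1, 2 and 3 they were -0.138, -0.068 and -0.301, so the groups overlapped. Gene length went with only part of the channel median: lists matched on span and expression had a median of -0.04, against -0.18 for the channel list. The channel median stood at percentile 0 of 10000 such lists, whose central 95% ran from -0.08 to 0.00081. Members of those lists were drawn independently, while the channel list had an estimated inter-gene correlation of 0.16, so the percentile overstates the evidence. Tissue from neighbouring regions is a candidate explanation: with the choroid plexus score as a covariate the median was -0.0323 (adjusted p = 0.073). Without cKO replicates 1 and 3, where 1 cKO library remains, it was -0.05. Both fits rest mainly on cKO replicate 2, so they cannot tell such tissue from other differences of that library. Striatal tissue went less with the lower channel genes, as the list kept a median of -0.17 with the striatal score as a covariate (adjusted p = 6.9e-06). A lower share of neurons stays open, since oligodendrocyte and endothelial medians were 0.33 apart but the difference of the 2 scores overlapped between the groups.

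Choroid plexus transcripts were high in cKO replicates 1 and 3. All 12 markers on the list lay above the other 4 libraries in both, with Ttr at 125 and 803 CPM by library size. That count restates the observation and would come out alike for any source, so choroid plexus tissue carried over at dissection stays open. The genotype stays open too, although cKO replicate 2 was at -0.33 and thus below the WT mean.

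The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. With 0 genes in the real split, all 10 splits give as many by definition, so their number says nothing about chance. The highest other gave 96 genes, with WT replicates 1 and 2 and cKO replicate 2 against the rest, which points to a structure of the samples that sets apart the libraries with choroid plexus transcripts and WT replicate 3. Early response members past the threshold over the list alone numbered 17 in the real split and at most 0 in the others, so 1 of 10 splits gave as many. The list's median was 0.65 in size in the real split and at most 0.47 in the others, again 1 of 10. For gene lists, 4 of 10 splits gave as many as the real 16, with 19 the highest other. For the correlation with gene length, 4 of 10 were as large as the real 0.10, with 0.19 the highest other.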
